A study of Arabidopsis thaliana with 7 samples.

How the data were processed

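Transcript levels were measured on 7 Affymetrix ATH1 arrays, a 1-colour platform hybridised with biotin-labelled RNA of Arabidopsis thaliana seedlings. The titles put 4 arrays in a Col-LUC wild-type group, 1 array in a C24-LUC wild-type group and 2 arrays in a sta1 group, and replicate numbers were taken from the same titles. Per the labels' protocols, seedlings grew for 2 weeks at 22 °C on MS agar with 3% sucrose. Each day had 16 h of light and 8 h of darkness. The titles give every sample as untreated. The growth text attached to both sta1 samples names another mutant, ice1, and speaks of growth before being treated. Their titles name sta1 and no treatment, and the titles were followed. The labels do not say that the samples came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

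Per the labels, the authors computed the deposited values with MAS5 as signal intensity per probe set and scaled each array to a target of 500. The MAS5 version is not given in the sources used here. In the deposited intensity values, the mean of the middle 96% of signals lay between 500.041 and 500.043 on every array, and the lowest signal was 0.1. After 64 control probe sets were left out, 22746 probe sets of plant genes remained. Detection calls were not used here. All columns of per-sample values were mapped to a sample.

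Signals under 50 were set to 50 and then converted to log2, so a fold against a group whose arrays all lie at 50 is a lower bound and is written as "at least". Probe sets with a signal of at least 100 on at least 2 arrays were tested, which kept 15673 probe sets, or 68.9%. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. The comparison of sta1 with wild type used 2 sta1 arrays and all 5 wild-type arrays. The comparison of C24-LUC with Col-LUC used a fit of 3 groups, in which the lone C24-LUC array was assumed to vary like the other groups. No array count gives a depth, and the number of arrays limits the precision of every value.

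Probe sets were named from the platform annotation table supplied with the files, matched by gene identifier to a RefSeq gene table of the TAIR10.1 assembly. In that table, 13513 probe sets had 1 gene, 503 had several and 8730 had none assigned, and 13436 of the genes matched the reference. Genes were named only from probe sets with 1 gene, which covered 8520 of the tested probe sets; a gene without a symbol is given by its locus. The levels of STA1, FLC and FRI, and the relation of intron content to the differences, were not analysed here.

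The groups, tests, thresholds, alternatives and 19 gene lists were fixed before the data were examined. The lists stood for the cold and CBF regulon, abscisic acid and drought, the spliceosome, SR proteins, mRNA decay, heat shock, oxidative stress, photosynthesis, ribosomal proteins, salicylic acid defence, jasmonate, flavonoid and anthocyanin synthesis, the cell cycle, the clock, flowering, senescence and starvation, and root, seed and floral markers. Together with STA1 they held 387 loci, of which 70 had a probe set with 1 gene. Each gene was represented by its probe set with the highest mean signal. Lists with at least 3 tested genes, 9 in all, were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 9 lists. A count "adjusted over the list alone" corrects for the members of that list only. A further 17 gene families were defined after the values had been opened and before their tests were run.

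The rule for named genes, also fixed in advance, took the 10 called probe sets with the largest difference in each direction that had 1 gene and lay beyond all wild-type arrays in both sta1 arrays. It added up to 4 called members of each list or, for a list with none, up to 2 members with the smallest p as values only. For C24-LUC it took the 5 largest differences in each direction outside the range of the Col-LUC arrays.

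The procedure was tested on simulated data with 200 changed probe sets among 15673. For sta1 against wild type it recovered 45 of 100 changes of 2-fold and 96 of 100 changes of 4-fold, with 9 false calls. For C24-LUC against Col-LUC it recovered 15 and 86 of 100, with 10 false calls. The simulated noise was independent between arrays, with no lot or session structure and an equal spread in every group. These rates therefore need not hold for the real arrays. The alternatives covered the floor, the filter, quantile normalization, median centring, the intensity trend, array weights, each array left out in turn, the choice of wild-type arrays and the replicate number as a block. Chip lot as a block, the arrays of the same calendar year, Col-LUC 2 and 4 left out together, the pair of arrays from 1 hybridisation session and, for C24-LUC, a filter on 1 array were added after seeing the data. The arrays of the same calendar year as sta1 left only Col-LUC 1 and C24-LUC as wild type. Hybridisation session as a block left no residual degrees of freedom, so that fit gave no test.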

Results

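Transcript levels of sta1 and wild-type seedlings were compared on 7 ATH1 arrays. STA1 is named in the series title as a nuclear protein required for splicing of mRNA precursors. Wild type comprised 4 Col-LUC arrays and 1 C24-LUC array, Col and C24 being natural strains of Arabidopsis, and sta1 comprised 2 arrays. The level of STA1 itself was not analysed here, so the labels of the sta1 arrays were not checked against it. The median signal per array lay between 208 and 216, and between 63.9% and 65.3% of probe sets reached a signal of 100. At least 22750 probe sets differed between any 2 arrays, which excludes copied files only, and each array was counted as the labels give it, as 1 sample.

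The first principal component carried 50.2% of the variance and the second 20.7%. Both sta1 arrays lay at 45.9 and 46.1 on the first component, Col-LUC 1 at 19.8, and the other Col-LUC arrays between -48.0 and -14.0. C24-LUC lay apart on the second component, at 56.2. Col-LUC 1 shared a chip lot with both sta1 arrays and a hybridisation session with sta1 1. Across probe sets, which are not independent replicates, Col-LUC 1 correlated with sta1 1 at r = 0.971, while pairs of Col-LUC arrays lay between 0.918 and 0.970.

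**Figure D1:**
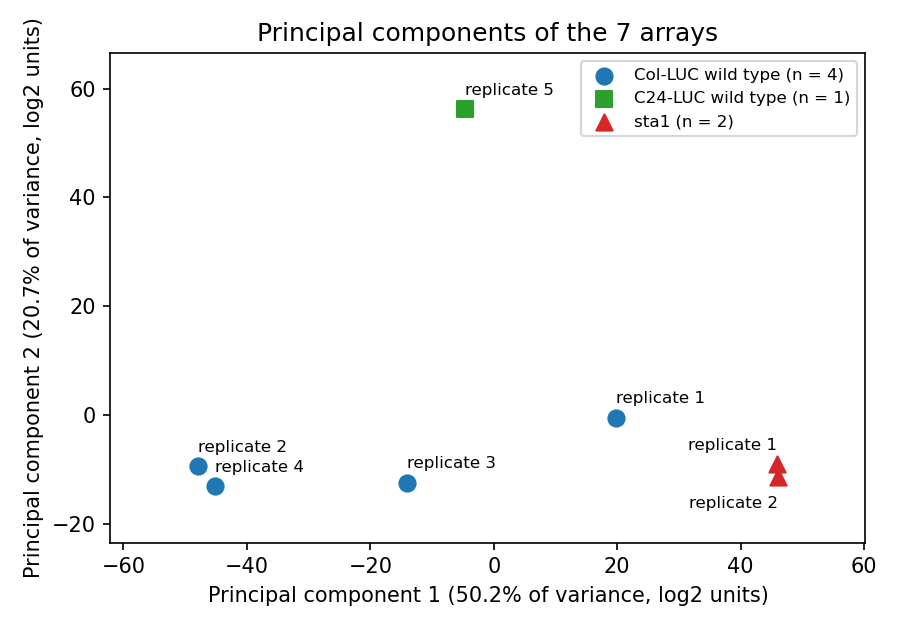
The 7 arrays on the first principal component (horizontal axis, 50.2% of the variance) and the second (vertical axis, 20.7%) of the log2 signals of the tested probe sets, both in log2 units, with 1 point per array. The sta1 arrays lie at 45.9 and 46.1 on the horizontal axis, and Col-LUC 1, at 19.8, is the wild-type array nearest to them.

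The comparison of sta1 with wild type asked which transcripts differ in seedlings of the splicing factor mutant, which the titles give as untreated. The largest rise among the named genes was that of AT2G04050, a MATE-type efflux transporter, which was 21.8-fold higher in sta1 (log2 difference 4.44 ± 0.68, SE, 2 sta1 and 5 wild-type arrays; adjusted p = 0.0281). NDB4, an external NAD(P)H dehydrogenase of mitochondria, lay at the floor on all wild-type arrays and was at least 9.55-fold higher (3.26 ± 0.30, limma adjusted p = 0.00642). Over the alternatives the difference of NDB4 reached 4.97 and that of AT2G04050 reached 4.93, so their order depends on the floor. AT2G21640 rose by 3.12 ± 0.37 on the log2 scale, AT5G51440, a small heat shock protein of mitochondria, by 2.87 ± 0.40, BHLH101, a regulator of the iron deficiency response, by 3.02 ± 0.52, and ICL, the isocitrate lyase of the glyoxylate cycle, by 2.85 ± 0.50. The other genes among the 10 largest rises were AT2G41730 (3.88), AT5G60250 (3.12), AT2G18190 (3.02) and AT2G03130. AT5G60250 lay at the floor on 4 of the 5 wild-type arrays, so its value depends on the floor. AT2G03130 lay at the floor on all wild-type arrays and was at least 7.17-fold higher.

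Among the lower genes, AT3G46490 was 5.89-fold lower in sta1 (log2 difference -2.56 ± 0.31; adjusted p = 0.0160). PSAN, a subunit of photosystem I, fell by 2.09 ± 0.19 on the log2 scale from 13.20 ± 0.26 (SD, n = 5) to 11.11 ± 0.28 (SD, n = 2), with an adjusted p of 0.00642. AT1G51400, annotated as a small protein of photosystem II, fell by 2.11 ± 0.31. AT5G48490, a lipid transfer protein, was 4.28-fold lower. The remaining 6 of the 10 largest falls were AT2G34620 (-2.51), AT1G21500 (-2.42), AT2G29290 (-2.34), AT5G57345 (-2.25), AT5G44520 (-2.07) and AT3G61080 (-2.01). Between sta1 1 and Col-LUC 1, the arrays of 1 session, AT2G04050 differed by 3.13, NDB4 by 2.71, ICL by 1.40, PSAN by -1.59 and AT1G51400 by -1.33.

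**Figure D2:**
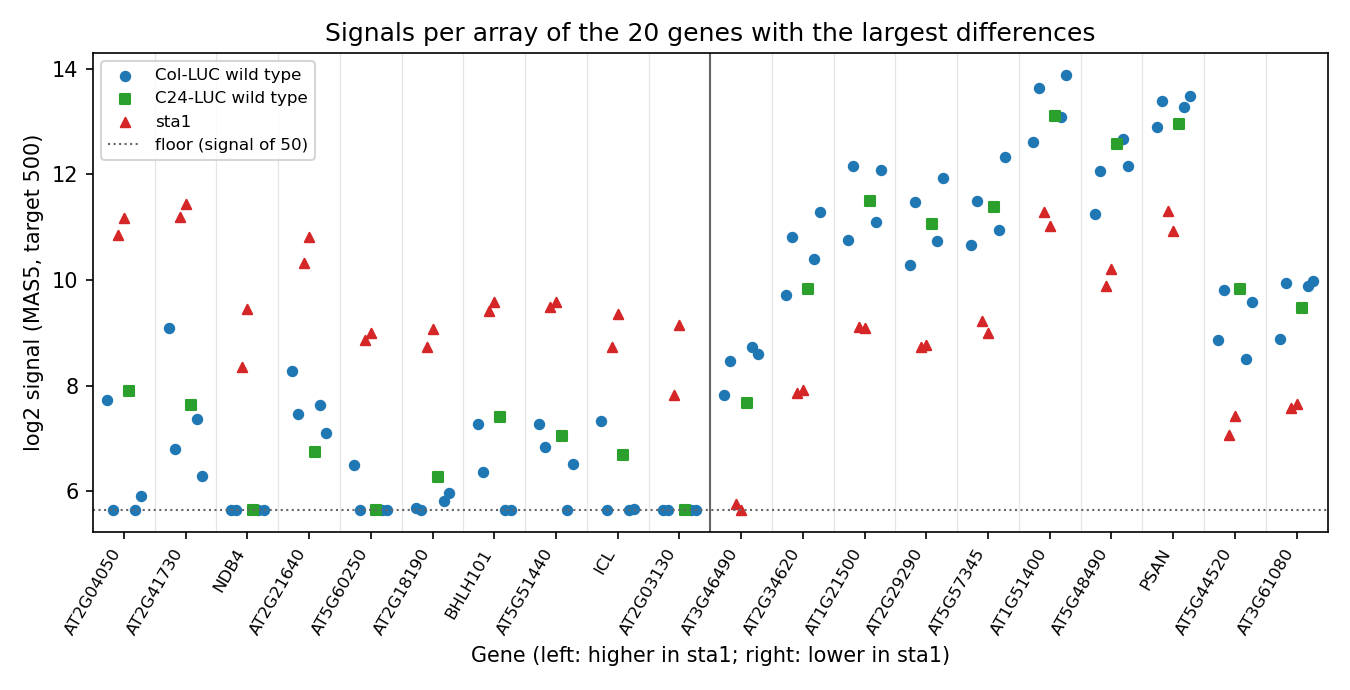
Log2 signal (vertical axis, values under the floor of 50 drawn at the floor, dotted line) of the 20 named genes with the largest differences that passed the test, with 1 point per array for Col-LUC, C24-LUC and sta1. In every gene shown both sta1 arrays lie beyond all 5 wild-type arrays, from AT2G04050, 21.8-fold higher, to AT3G61080, 4.03-fold lower.

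In all, 85 probe sets were higher and 120 lower in sta1 (limma), of which 46 and 58 had 1 gene, and 69 and 83 differed by at least 2-fold. Both sta1 arrays lay above all wild-type arrays in 2613 of the tested probe sets and below them in 2464, where chance gives 4.76% of them, or 746, in each direction. Among 200 probe sets chosen on the other 5 arrays, 97.0% differed in the same direction between sta1 1 and Col-LUC 1, with a median ratio of 0.513 between the 2 differences, and over all tested probe sets 69.3% did. The number of calls rested on single arrays: it was 647 higher and 734 lower without Col-LUC 1, 16 and 37 without Col-LUC 2, 18 and 25 without Col-LUC 3, 17 and 40 without Col-LUC 4, and 0 and 0 without either sta1 array, with 1761 and 1487 probe sets at an unadjusted p under 0.05 against 3680 in the full fit. Of the 22 named genes that passed, 22 did so without Col-LUC 1, 7 without Col-LUC 2, 9 without Col-LUC 3, 11 without Col-LUC 4 and 0 without either sta1 array. With only the arrays of the same calendar year as sta1, where Col-LUC 1 and C24-LUC are the wild type, limma also called 0 probe sets. At an unadjusted p under 0.05 there were 2375. The planned replicate block called 0 as well, with 2198 at an unadjusted p under 0.05. Chip lot as a block sets sta1 against Col-LUC 1 alone. The called differences then had a median size of 1.08, against 1.28 without the block. These probe sets were chosen in a fit that used Col-LUC 1, so the size kept against that array depends in part on the choice.

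Nuclear genes of photosynthesis, 7 tested of 40 in the list, were lower in sta1. Of these 7, 3 fell over all probe sets and 7 when adjusted over the list alone, and the median log2 difference was -0.55. Besides PSAN, LHCB4.1, a light-harvesting protein of photosystem II, fell by 0.68 ± 0.11 (adjusted p = 0.0360) and PSBW, a photosystem II subunit, by 0.81 ± 0.14 (adjusted p = 0.0421). PSAE-1, ATPC1, PRK and RCA had differences of -0.55, -0.31, -0.36 and -0.21 and did not pass over all probe sets. The list passed camera (adjusted p = 4.17e-06), and the adjusted p was 0.214 with an estimated correlation. The median difference was -0.37 between sta1 1 and Col-LUC 1, with all 7 members lower, and -0.41 with chip lot as a block. The 69 plastid-encoded genes, a family defined after the values were opened, had a median of -0.06 (camera adjusted p = 0.275) and 0 calls by limma. In the limma fit 9 of these 69 had an unadjusted p under 0.05, a smaller share than the 3680 of all 15673 tested probe sets.

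Spliceosome genes lay higher in sta1 as a group. All 17 tested members had a positive difference, with a median of 0.40, but 0 passed over all probe sets and 4 did when adjusted over the list alone. The members with the smallest p were AT1G28060, a component of the U4/U6 particle also known as RDM16, at 0.76 ± 0.15 (adjusted p = 0.0534), and AT2G42270, with a ratio of 2.82 (adjusted p = 0.0618). The list passed camera (adjusted p = 1.43e-05), and the adjusted p was 0.110 with an estimated correlation. Between sta1 1 and Col-LUC 1 the median difference was 0.23, with all 17 members positive, and it was 0.29 with chip lot as a block.

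Anthocyanin genes had the largest median among the 9 lists tested, over all arrays. The 4 tested members, DFR (3.03), AT4G14090 (3.03), UF3GT (2.96 ± 0.60; adjusted p = 0.0598) and AT5MAT (2.23 ± 0.54; adjusted p = 0.0781), code for late steps of pigment synthesis; 0 passed over all probe sets and 4 when adjusted over the list alone. The median was 3.00 and camera gave an adjusted p of 0.000847, which was 0.269 with an estimated correlation and 0.0529 by fry. The median was 0.64 between sta1 1 and Col-LUC 1, 0.85 with chip lot as a block and 1.65 over the arrays of the same calendar year. Col-LUC 1 itself lay above the other Col-LUC arrays in UF3GT, at a signal of 724.2 against 118.3 to 177.0.

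Lists of RNA turnover and translation did not pass camera over all arrays in the main setting. The 10 mRNA decay genes had a median of 0.29 (camera adjusted p = 0.0598), with AT5G38890 at 0.80 ± 0.17 and AT2G39260 at 0.37 ± 0.15, and 1 passed when adjusted over the list alone. The 4 ribosomal protein genes had a median of 0.26 (adjusted p = 0.0598), with AT3G09630 at 0.28 and AT5G02870 at 0.31. Without Col-LUC 3 both lists passed, each with an adjusted p of 0.0470, and without Col-LUC 1 the ribosomal list passed at 0.0449. The mRNA decay list also passed camera without a filter (0.0173) and with median centring (0.0496). It passed by fry too (0.0160), which tests the members against no change and not against the other genes. Over all of these tests the adjusted p lay between 0.0160 and 0.269. The ribosomal list also passed without a filter (0.0276), with quantile normalization (0.0384), median centring (0.0496) and array weights (0.0499), within a range of 0.0276 to 0.468. Between sta1 1 and Col-LUC 1 the medians were 0.15 and 0.05.

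Stress lists moved in few members. Of 4 heat shock genes AT5G51440 rose, and the list had a median of 0.15 (adjusted p = 0.577). Of 2 oxidative stress genes AT2G21640 rose, and GSTU25, a glutathione transferase, had a difference of 2.55, which was 0.44 between sta1 1 and Col-LUC 1. The 5 tested genes of the cold regulon, which encode mostly protective proteins of cold acclimation, had a median of -0.66 (adjusted p = 0.182) and 0 calls by limma, with COR47 at -0.66 ± 0.27 and COR15B at -1.48 ± 0.66. In these 2 genes the differences between sta1 1 and Col-LUC 1 were -0.13 and -0.36.

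The remaining lists had no member that passed over all probe sets. In salicylic acid defence, WRKY53 had a difference of 1.59 ± 0.61 and SAG101 of 0.86 ± 0.43. Between sta1 1 and Col-LUC 1 these were 0.88 and 0.69. The jasmonate-responsive defensins PDF1.2b and PDF1.2 had differences of -0.60 ± 1.70 and -0.46 ± 1.86, smaller than their errors. They were -1.89 and -2.51 between sta1 1 and Col-LUC 1, with a median of -3.26 with chip lot as a block, and were positive in some settings, up to 0.51 and 0.55 without sta1 2. The senescence gene WRKY6 had a difference of 0.81 ± 0.30 and the clock gene GI of -1.13 ± 0.52, which was -0.07 between sta1 1 and Col-LUC 1. The cell cycle list had a median of 0.26 (adjusted p = 0.440), with PRL, also known as MCM7, at 0.36 and AUR2 at 0.26. The root markers had a median of -0.19 (camera adjusted p = 0.577), with PYK10 at -0.19 and EXPA18 at -0.31. Between sta1 1 and Col-LUC 1 their median was -0.49, with all 3 members lower, and it was -0.47 with chip lot as a block. The lists of abscisic acid and drought, SR proteins, flowering, seed markers and floral markers, 5 in all, held no tested gene.

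**Figure D3:**
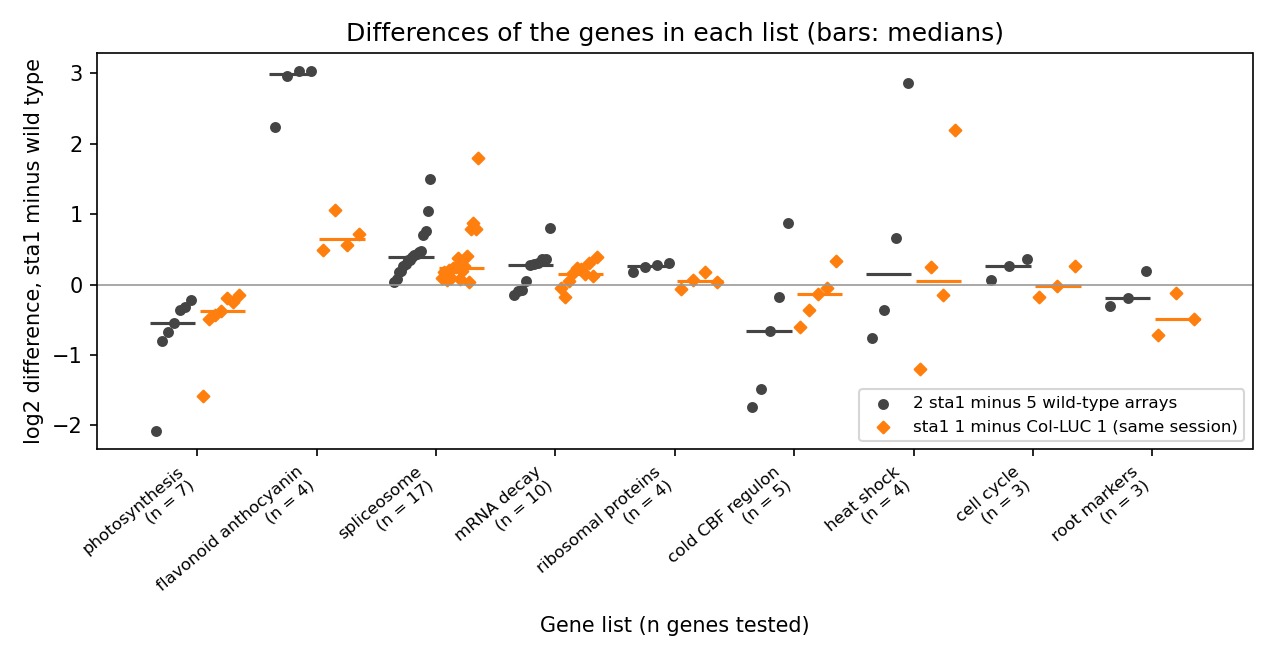
Log2 difference between sta1 and wild type of each member of the 9 tested gene lists (vertical axis), with 1 point per gene and a bar at the median, over all arrays (circles) and between sta1 1 and Col-LUC 1 alone (diamonds). The medians over all arrays were -0.66 for the cold regulon, -0.55 for photosynthesis, 0.40 for the spliceosome and 3.00 for anthocyanin synthesis, where the median between sta1 1 and Col-LUC 1 was 0.64.

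The comparison of C24-LUC with Col-LUC asked how far the 2 wild-type strains differ, since both serve as wild type. ECS1, a cell wall protein, was 159.6-fold lower on the C24-LUC array (log2 difference -7.32 ± 0.28, SE, 1 and 4 arrays; adjusted p = 0.000172). AT4G15390, AT4G20480, AT1G23960 and AT5G45500 lay at the floor in C24-LUC and were at least 43.7-fold, 21.2-fold, 18.4-fold and 16.5-fold lower. THI2.2, a thionin, was 20.6-fold higher (4.36 ± 0.33; adjusted p = 0.00202), and AT1G61500, AT5G15360, AT4G22450 and AT1G09500 were higher by 4.26, 3.69, 3.52 and 3.24 on the log2 scale. All 10 genes lay outside the range of the 4 Col-LUC arrays.

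In C24-LUC, 32 probe sets were higher and 182 lower (limma), of which 19 and 104 had 1 gene, and 28 of the lower lay at the floor on the C24-LUC array. The excess of lower calls held only among probe sets that reach a signal of 100. With that signal on 1 array, which keeps probe sets high on C24-LUC alone, 62 were higher and 183 lower. Without a filter 234 were higher and 158 lower, and 154 of the higher ones lay under 100 on every array. None of the 9 gene lists passed camera, each with an adjusted p of 0.973, and the lowest unadjusted p was 0.115 by camera and 0.0326 by fry, both for the cell cycle list. C24-LUC is represented by 1 array in a chip lot of its own, so the strain cannot be told apart from that array, lot or session. The counts, higher and lower, were 170 and 310 without Col-LUC 1, 17 and 99 without Col-LUC 2, 14 and 93 without Col-LUC 3, 18 and 90 without Col-LUC 4, and 5 and 48 without either sta1 array, where 7 of the 10 named genes passed.

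The last comparison asked whether sta1 differs from Col-LUC in the direction of C24-LUC. Of the probe sets called in each, 0 were higher in both where 0.198 would be shared by independent lists, 2 were lower in both where 1.17 would be, and 2 were called in opposite directions. Across probe sets, which are not independent replicates, the differences correlated at r = 0.268. Simulated unchanged groups, with all arrays simulated and 4 of them shared as Col-LUC, gave 0.254. Sharing the controls alone thus gives such an r, so the 0.268 cannot show a shared direction. The covariance was 0.0826 against a simulated 0.0231. With the Col-LUC arrays split between the comparisons, r lay between -0.0927 and 0.260, with a mean of 0.146, and it was negative when sta1 was set against Col-LUC 2 and 4.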

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

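The counts of other splits of the arrays, the test within the shared session and the test of RNA degradation were chosen only after the results they bear on had been seen. So were the bootstrap interval of the mixing share, the mixing test above the floor, the test of the filter and the chip lot block. The counts of called probe sets among those at least 4-fold lower or higher were also chosen afterwards.

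Some values stood far from the rest of their group of 4. Col-LUC 1 lay apart from the other 3 Col-LUC arrays in NDB4, at a signal of 42.0 against 6.80 to 11.1, all under the floor of 50 and so no measurable difference, in WRKY53, at 178.3 against 37.8 to 45.8, in UF3GT, at 724.2 against 118.3 to 177.0, in AT5MAT, at 276.8 against 63.7 to 83.9, and in AT3G61080, at 468.6 against 945.1 to 1005.2. The 25S rRNA control probe set had a signal of 1987.2 on Col-LUC 2 against 109.4 to 238.6 on the other Col-LUC arrays, and it also differed between sta1 2, at 1879.8, and sta1 1, at 475.9. These are 6 of 67 groups examined, where chance gives 3.35. Among 19 control probe sets of plant genes, which the comparisons did not use, 5 lay above all wild-type arrays on both sta1 arrays. They were the 5S rRNA control, 3.50-fold higher, and GAPDH controls at 1.60-fold, 1.64-fold, 1.43-fold and 1.36-fold, and 0 lay below. The actin control at the 3 prime end had a signal of 1024.6 in C24-LUC, 7.51-fold lower than in Col-LUC. A second actin control at that end was 5.98-fold lower. The matching 5 prime control, at 4950, lay within the Col-LUC range of 4526.3 to 5699.6. The actin ratio of 3 prime to 5 prime signal was thus 0.207 in C24-LUC against 1.35 to 1.68 in Col-LUC. The cause was not tested.

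The first pattern weighed is the difference between sta1 and wild type, 205 called probe sets. Only the real split, 1 of the 21 splits of the 7 arrays into 5 and 2, reached that number. Its share, 4.76%, is the smallest that 21 splits can give, so this count alone cannot exclude chance. The split that sets Col-LUC 2 and 4 apart called 164 and points to a structure among the wild-type arrays. Among 200 probe sets chosen without the pair of arrays from the shared session, 97.0% differed the same way between sta1 1 and Col-LUC 1, against 91.5% of the 2385 at an unadjusted p under 0.05 in the other arrays and 69.3% of all tested, which argues against a lot or session effect as the whole cause, while the median ratio of 0.513 leaves a part of the sizes open. With chip lot as a block, sta1 is set against Col-LUC 1 alone. The 1 residual degree of freedom, in place of 5, comes only from the 2 sta1 arrays. The errors of that fit hold no spread between wild-type arrays, so only sizes are given. The 205 had a median size of 1.08 (quartiles 0.78 and 1.46) with the block and 1.28 (0.99 and 1.89) without it. Their sign was fixed by how they were chosen, and their size depends in part on it, since the choice used Col-LUC 1. The ratio of 0.513 comes from probe sets chosen without the session pair. AT2G04050 had a difference of 4.44 without the block and 3.29 with it, and PSAN of -2.09 and -1.78. The difference of NDB4, 3.26 in both fits, could not change, since all wild-type arrays lie at the floor in this gene. The genotype remains a hypothesis for the shared direction, since it was tested on the same arrays that showed it.

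The second pattern is the place of Col-LUC 1, which lay toward sta1 on the first principal component. If the shared session were the cause, its deviation from the other Col-LUC arrays could track the difference between sta1 1 and sta1 2; across probe sets r was 0.192, between the bounds set for and against. If the shared chip lot were the cause, it could track sta1 minus C24-LUC, where r was 0.346, but all sta1 arrays share that lot, so lot and genotype cannot be told apart here. If sta1 RNA were mixed into the sample, 1 share should hold for all probe sets; in 50 near the floor (median 57.0%, range -87.9% to 437%) the upper quartile was 2.31 times the lower, over the bound of 2 set in advance, but the 95% bootstrap interval of 1.66 to 5.58 includes it. In probe sets above the floor, chosen without Col-LUC 1, the quartiles lay 36.8 points apart for 141 higher ones, wider than the 13.6 to 16.4 of the other Col-LUC arrays but not than the 41.1 between the sta1 arrays, and 34.8 apart for 172 lower ones, wider than the 7.53 between the sta1 arrays but 0.588 of the widest other Col-LUC array, 59.1; the median shares of 48.3% and 70.6% differ, but so do those of Col-LUC 3, -6.18% and 23.3%, so mixing stays open, and no biological explanation was tested.

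The third pattern is the excess of lower over higher calls in C24-LUC, 182 against 32, which holds only among probe sets that reach a signal of 100, since without a filter 234 were higher and 158 lower, 154 of the higher ones being under 100 on every array. The filter needs 2 arrays and so removes probe sets high on the C24-LUC array alone, but with 1 array enough 183 were lower and 62 higher, a ratio of 2.95 that was 1.55 without Col-LUC 1 and at least 2.36 without any other array, which argues against this need as the whole cause, though not as a part. RNA degradation is argued against by the GAPDH ratio of 3 prime to 5 prime signal, 1.02 in C24-LUC and 0.979 to 1.15 in Col-LUC, and by the ubiquitin ratio, 1.18 against 1.58 to 1.65. Sequence differences between C24 and the probes could lower signals. The ratio of probe sets at least 4-fold lower to at least 4-fold higher, 1.13, lay within the range of single Col-LUC arrays, 0.434 to 1.65. That range was the bound set in advance against sequence differences. It proved wrong because 0 of the 21 to 36 probe sets at least 4-fold lower on a Col-LUC array were called. In C24-LUC 60 of the 85 at least 4-fold lower were called, and 17 of the 75 at least 4-fold higher. Large differences were thus closer to even between the directions than the calls, so the ratio does not describe the calls. Sequence differences stay open, as does a difference in expression between the strains, which was not tested apart from the array.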

How the results depend on the processing

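Chip lot as a block, the arrays of the same calendar year, Col-LUC 2 and 4 left out together, the pair from 1 session and the filter on 1 array were chosen after seeing the data; the other alternatives were planned.

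Calls of sta1 probe sets, higher and lower, numbered 141 and 125 with a floor of 100, 60 and 28 without a filter, 68 and 71 without the intensity trend, and 1727 and 1741 with array weights. The share of higher calls was 41.5% in the main setting, 53.0% with a floor of 100 and 68.2% without a filter. Leaving out arrays in turn gave 0 to 647 higher and 0 to 734 lower, and leaving out Col-LUC 2 and 4 gave 7 and 16. Chip lot as a block gives sizes only, and the arrays of the same calendar year gave 0 and 0 by limma, with 2375 at an unadjusted p under 0.05. These last settings, and those without a sta1 array, fit fewer samples or leave 1 or 2 residual degrees of freedom; for the other changes the cause was not tested. Using only Col-LUC as wild type is the fit without C24-LUC and gave 96 and 99. The arrays of the same calendar year as sta1 left only Col-LUC 1 and C24-LUC as wild type.

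With the replicate block limma called 0 higher and 0 lower, with 2198 at an unadjusted p under 0.05 and 1 residual degree of freedom. Deviations of same-numbered arrays correlated at 0.204 for replicate 1, whose arrays share a chip lot and session, and -0.0106 for replicate 2. With 2 sta1 arrays these values cannot show whether the numbers pair the samples, so pairing stays open and the block is given only as an alternative. The gene lists called numbered 3 under the block, as in the main setting.

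C24-LUC calls, higher and lower, numbered 69 and 135 with a floor of 100, 234 and 158 without a filter, 62 and 183 with a filter of 100 on 1 array, 21 and 178 with a filter of 200, 91 and 309 with array weights, and 5 and 48 with only Col-LUC and C24-LUC arrays. Leaving out arrays in turn gave 5 to 170 and 48 to 310. Against 32 and 182 in the main setting, the share of higher calls was 59.7% without a filter, where 202 of the higher calls lay outside the probe sets of the main filter and 154 of these were under 100 on every array. For the other changes the cause was not tested.

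Gene lists called in sta1, 3 in the main setting, numbered 5 without a filter, 5 with median centring, 3 to 5 with arrays left out in turn, and 0 with an estimated correlation; the cause was not tested. The correlation of sta1 and C24-LUC differences was 0.107 and 0.125 under 2 of the splits of Col-LUC and reversed to -0.0927 when sta1 was set against Col-LUC 2 and 4, with fewer arrays on each side. Of the tested values of called sta1 genes under alternatives, each fit counted once, 220 kept the call and 198 lost it. For C24-LUC genes 142 kept it and 14 lost it, with 7 and 3 in each of 3 nearly equal fits that lack 1 or both sta1 arrays. For called lists 59 kept it and 4 lost it. Over the alternatives the adjusted p lay between 9.84e-07 and 0.214 for photosynthesis, 5.55e-07 and 0.110 for the spliceosome, 2.77e-05 and 0.269 for anthocyanin synthesis, 0.0160 and 0.269 for mRNA decay, and 0.0276 and 0.468 for ribosomal proteins, each with 1 sign throughout. The root markers had a mean of -0.57 with chip lot as a block, a fit that gives sizes only. The cold list passed camera over the arrays of the same calendar year (mean -0.50, adjusted p = 0.0428, range 0.0428 to 0.468). Low signals limit the result: genes at the floor have bounds only. The level of STA1 and intron content were not run.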

Other observations

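The gene families below, the single genes named outside the fixed rule and the marker lists were chosen after the values had been opened; the tests of the families and of the hypotheses were set before their own results were seen.

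Ribosomal protein genes, taken as a wide family, lay slightly higher in sta1. Of 83 tested members 81 had a positive difference, with a median of 0.35, though 0 passed singly, and camera gave an adjusted p of 4.58e-14, which was 0.593 with an estimated correlation. The median was 0.14 between sta1 1 and Col-LUC 1, with 70 members of the same sign, and 0.12 with chip lot as a block. All 11 tested subunits of nuclear RNA polymerases had positive differences, with a median of 0.54 (adjusted p = 0.000519, and 0.593 with an estimated correlation) and 0.41 between sta1 1 and Col-LUC 1; NRPE7 had a difference of 0.72, NRPC2 of 0.61 and NRPA1 of 0.58. The ubiquitin family, 31 genes of which 23 were positive, had a median of 0.25 (adjusted p = 0.0272, and 0.401 with an estimated correlation), with UBP25 at 0.88 and UBP23 at 0.69. That call was lost without Col-LUC 1 (adjusted p = 0.0543), without sta1 2 (0.0721) and over the arrays of the same calendar year (0.0524), within a range of 0.0126 to 0.0721 over the settings at the preset correlation. The other 14 of 17 families did not pass in the main setting, with adjusted p between 0.275 and 0.986. With the replicate block the BGLU glucosidases passed (adjusted p = 0.0484, range 0.0484 to 0.828), with 1 of 11 positive, and in C24-LUC 0 families passed.

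Some called genes outside the fixed rule are named here, chosen after their values were seen. LHCB4.2, a second form of the light-harvesting protein, fell by 1.25 on the log2 scale, and LPA19 and PSB27, which act in assembly and repair of photosystem II, fell by 1.66 and 0.77. TAPX, the thylakoid ascorbate peroxidase, fell by 1.54, and HEME2, an enzyme of tetrapyrrole synthesis, by 0.69. PYE, a regulator of iron homeostasis, rose by 1.31. AT2G04070, a MATE-type transporter, rose by 2.65. PPR596, a pentatricopeptide repeat protein, rose by 1.08, and ATO, a homologue of a splicing factor subunit, by 1.05.

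A wider response to mitochondrial dysfunction was tested as a hypothesis, because NDB4, AT2G21640 and AT5G51440 were among the largest rises. Of 5 further genes known to respond to such dysfunction, 3 lay above all 5 wild-type arrays on both sta1 arrays: AT5G43450 at 2.21, GSTU25 at 2.55, whose value the oxidative stress list had already given, and AT5G09570 at 2.42. Between sta1 1 and Col-LUC 1 these differences were 1.84, 0.44 and 0.46, since Col-LUC 1 itself lay high in the last 2, with GSTU25 at a signal of 777.6 against 150.6 to 235.7 on the other Col-LUC arrays. AT5G64400 and AT4G01870 had differences of 0.30 and 0.46. The count of 3 lies between the 4 set in advance for the hypothesis and the 1 set against it, so it may hold but remains open.

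BZIP60, a transcription factor of the unfolded protein response, rose by 1.24 in sta1. Of 5 genes of folding and quality control in the endoplasmic reticulum, 0 lay above all wild-type arrays, with CRT1b at 0.23 and ATERDJ3B at 0.22. That count meets the bound set in advance against a wider rise. Only 16.7% of all tested probe sets lay above in this way, so 0 of 5 cannot decide the question.

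A comment in the scanner record of Col-LUC 2 names ABA, while its labels state no treatment. The hypothesis that this sample was treated was tested on 10 genes known to be induced by abscisic acid, 3 of which the cold list also holds. Their median difference between Col-LUC 2 and the other Col-LUC arrays was 0.85, between the bounds set for and against. LEA4-5, AtLEA4-1 and LEA18 lay under the floor on some or all of the other Col-LUC arrays. LEA18, for example, had signals of 1.4, 2.9 and 42.2 there, against 97.1 on Col-LUC 2. The floor limits these differences, at 0.84, 0.92 and 0.96, and AtLEA4-1 and LEA18 also failed the filter. The median thus depends on the floor and cannot decide the question. Treatment may explain part of the difference and remains open. COR15A had a signal of 4117.5 on Col-LUC 2, 2250.4 on Col-LUC 4 and 411.3 to 443.4 on the others, so that Col-LUC 4, without such a comment, was also higher.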
